A study of Mus musculus with 4 samples.

How the data were processed

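Total RNA from CD45-negative lung cells of C57BL/6 mice, taken 10 days after PBS or BLM was given into the trachea, was labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The 4 samples fall into 2 groups of 2 by the treatment in their labels. Nothing in the labels says that the 2 samples of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

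The deposited values are log2 expression values per transcript cluster, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, scales the arrays to a common distribution and summarises probes into 1 value. Program versions, the array build and any later scaling are not given in the sources used here. The array medians were 5.44 to 5.49 and the highest values 19.56 to 19.87. On each array 571 to 617 clusters lay above 16, the log2 range of a 16-bit scanner, so the values hold a scaling beyond the scanner's own range that is not stated, and differences were taken on the scale as deposited. No detection calls were used here, so genes near the floor were kept in the test, and differences of dim genes are compressed toward 0. The number of arrays limits the precision. Among control probes, exons were told from introns with an area under the curve of 0.801 and 0.809 on the PBS arrays and 0.824 and 0.832 on the BLM arrays. The hybridisation spike-in cre lay 3.62 to 3.94 log2 units above bioB on all 4 arrays. The poly-A spike-in dap, added to RNA before labelling, lay at 6.95 and 6.90 on the PBS arrays and at 4.51 and 5.90 on the BLM arrays, while thr lay at 4.40 and 4.61 against 3.95 and 4.80, lys at 3.87 and 3.90 against 3.69 and 3.98, and phe at 3.61 and 3.66 against 3.67 and 4.08.

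Of 72688 features, 6732 were controls and 65956 were transcript clusters. The platform annotation lists 32750 of these, 30604 with 1 gene symbol and 2146 with several, and 33206 clusters are unnamed here. Through Entrez identifiers, 827 symbols were updated, and 29837 of the tested symbols are in the RefSeq gene table. Clusters with several symbols or none stayed out of the comparison. For the 355 genes with more than 1 cluster, the cluster with the highest mean over the 4 arrays was kept, which left 30142 genes. Of these, 447 share identical values with another gene, and none of them is named in the text.

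Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with its default prior, two-sided), with Benjamini-Hochberg adjustment over all 30142 genes and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom and 3.33 prior degrees of freedom. The median standard error of a log2 difference was 0.0969, the median width of its 95% interval to either side was 0.244, and the smallest difference called was 0.291. A second count took genes that also differed by at least 1 log2 unit. In simulated data for BLM against PBS over 30142 genes, a change of 0.5 log2 units was recovered in 0 of 68 genes, of 1 unit in 40 of 66 (60.6%) and of 2 units in 64 of 66 (97%), with 0 false calls. No other genes were shifted there, whereas 7629 passed in the data. The adjustment is stricter where fewer genes change, so these shares do not give the recovery in the data, where differences down to 0.291 were called.

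Before the data were examined, 44 gene lists of lung cell types, fibrosis, inflammation and stress were fixed, together with a sex-linked list used only to check the samples. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 44 lists. Camera with a correlation estimated from the 2 residual degrees of freedom was run beside it. That test refers its statistic to 2 degrees of freedom, and its lowest adjusted p was 0.226. By fry, 35 lists moved on balance 1 way and 44 changed in either direction, a test that does not compare a list with other genes. On simulated data with 44 lists, both lists given a shift were recovered and 0 others were called. The simulated genes varied independently, so false calls from correlated genes within a list could not appear there.

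The genes named in the text followed a rule also fixed beforehand. It took the 6 highest and 6 lowest log2 differences among genes past the threshold, skipping unnamed transcripts, and a fixed panel whatever its result. For each gene list it took up to 4 members of main lists, or 2 of the others, with the largest absolute difference among those past the threshold. Genes outside this rule were named after their values were seen, as the text says.

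Alternatives fixed beforehand were the replicate number as a block, leaving out each array in turn, a filter on dim genes, the mean of a gene's clusters, a trended and robust prior, median centring, cyclic loess scaling and the estimated correlation. Leaving out the genes of the X and Y chromosomes was added after the Xist and Y-linked values were seen, and camera with each estimated correlation held fixed after the list results were seen.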

Results

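Gene expression was measured in the CD45-negative fraction of mouse lung, that is, lung cells without the surface marker of leukocytes, 10 days after phosphate-buffered saline (PBS) or bleomycin (BLM) was given into the trachea. Bleomycin is a DNA-damaging drug used to induce lung injury and fibrosis in mice. The data comprised 4 arrays, 2 from PBS-treated and 2 from BLM-treated C57BL/6 mice, with total RNA hybridised to 1 Affymetrix array per sample. The series has a single comparison, BLM against PBS, which asks how the non-leukocyte cells of the lung differ while fibrosis develops. Differences are given as log2 of BLM minus PBS with their standard error (SE), n = 2 arrays per group, and rose or fell is used only of genes past an adjusted p of 0.05 in the limma fit over 30142 genes. Genes named as exceptions, as members of a small count or as not passing were, unless they belong to the fixed panel, chosen after their values were seen.

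On the BLM arrays, most genes in the lists of matrix proteins, activated fibroblasts and macrophages rose (35 of 37, 13 of 23 and 15 of 20), and most in those of ciliated, secretory and alveolar type 2 epithelium fell (23 of 24, 10 of 13 and 16 of 20). Tnc, the matrix glycoprotein tenascin C, showed the greatest rise, by 6.58 (SE 0.10, adjusted p = 7.27e-05), or 95.6-fold. It was followed by Ctss, a lysosomal protease abundant in macrophages, at 5.49 (SE 0.13), Clec7a, a myeloid receptor for fungal glucan, at 5.43 (SE 0.18), and Sfrp1, a secreted Wnt antagonist, at 4.63 (SE 0.19). The secreted glycoprotein gene Scube1 rose by 4.43 (SE 0.09) and the cell adhesion gene Nrcam by 4.37 (SE 0.12). On the PBS arrays Clec7a and Nrcam lay at 5.84 and 5.55, below the median level of all genes, 6.03, so the sizes of their differences are not exact. Apart from Xist, the deepest falls were those of the drug-metabolising cytochrome P450 genes Cyp2b10, at -4.21 (SE 0.11), and Cyp2a4, at -4.13 (SE 0.11), and of the aldehyde oxidase gene Aox3, at -4.09 (SE 0.12). Cyp2a4 is nearly identical in sequence to Cyp2a5, so its value is uncertain as to which of the pair it reflects. The basophil protease gene Mcpt8 stood at -3.74 (SE 0.14) and the amino acid transporter gene Slc38a4 at -3.32 (SE 0.10).

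In all, 7629 of 30142 genes (25.3%) passed the threshold, 4582 higher and 3047 lower in BLM, and 1550 of them differed at least 2-fold, 848 higher and 702 lower. The share of calls that were higher was 60.1%, against 49.6% after cyclic loess scaling of the same arrays. The total was 4003 without BLM replicate 1 and 4379 without BLM replicate 2. The BLM and PBS values of a gene did not overlap for 63.3% of genes, where chance alone gives 33.3%. Arrays of a group lay close together, with a mean absolute difference of 0.157 log2 units between the PBS arrays and 0.134 between the BLM arrays, against 0.329 to 0.342 between groups. A fit without a BLM array takes its spread from the PBS pair alone, the wider of these, so a call lost there need not rest on that array. Across genes, which are not independent replicates, Pearson's r was 0.997 within either group and 0.979 to 0.981 between them.

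Sex-linked transcripts separated the arrays along the same line as the treatment. Xist, the RNA that silences the inactive X chromosome in female cells, was at 15.86 and 15.61 on the PBS arrays and at 5.60 and 5.43 on the BLM arrays, a difference of -10.22 (SE 0.12, adjusted p = 4.79e-05). The BLM values lay below the median level of all genes, 6.03, in the dim range where differences are compressed toward 0, so the size of this difference is not exact. The Y-linked genes Eif2s3y, Uty and Kdm5d were higher on the BLM arrays by 2.63 (SE 0.28), 2.44 (SE 0.23) and 2.14 (SE 0.13). The labels give no sex for any sample. Every difference between the groups described here is therefore also a difference between Xist-high and Xist-low arrays.

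**Figure D1:**
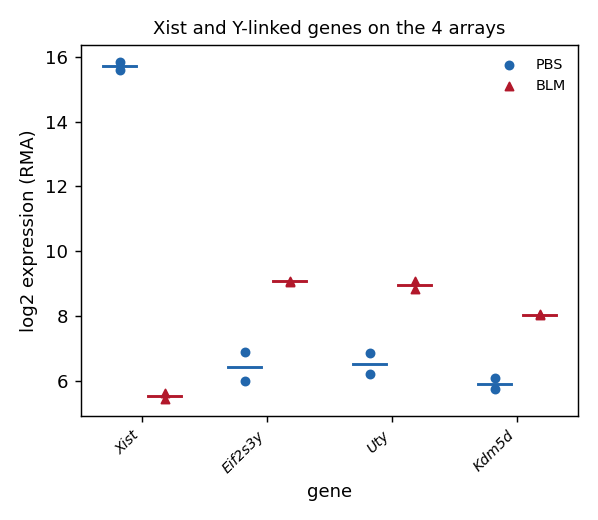
Log2 expression (vertical axis) of Xist and the Y-linked genes Eif2s3y, Uty and Kdm5d on each PBS array (circles) and BLM array (triangles), with a bar at each group's mean of 2 arrays. Xist lies at 15.86 and 15.61 on the PBS arrays and at 5.60 and 5.43 on the BLM arrays, and all 3 Y-linked genes lie higher on both BLM arrays.

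Matrix genes rose almost throughout. Of 37 measured matrix protein genes, 35 rose, 29 of them at least 2-fold, none fell and 2 did not pass, Dcn at 0.28 (0.16 to 0.40 without each array in turn and 0.11 with cyclic loess) and Col14a1 at 0.12 (0.06 to 0.17, and -0.04 with cyclic loess); adjusted over the list alone, 36 rose. Beside Tnc, the collagen genes Col1a1 and Col3a1 rose by 4.28 (SE 0.08) and 3.60 (SE 0.11), and the fibronectin gene Fn1 by 4.14 (SE 0.08), from a level of 13.61 to 17.75. Cthrc1, a secreted protein gene marking collagen-producing fibroblasts in fibrosis, rose by 1.02 (SE 0.11, adjusted p = 0.00306). The list shifted upward by camera (median 1.37, adjusted p = 3.8e-22). It had an adjusted p = 0.226 with an estimated correlation, the lowest that this test on 2 degrees of freedom gave any list. That test therefore says little of this list or of those below. The estimate for matrix proteins was -0.024 and was set to 0 in the test that held it fixed. There camera's adjusted p was 1.11e-29, in a more lenient test than that at the preset 0.01. Spp1, also on the fixed panel, was not analysed here.

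Among 17 genes of collagen crosslinking and processing, 12 rose, 3 fell and 2 did not pass (14 rose and 3 fell adjusted over the list alone). P4ha3, a collagen prolyl hydroxylase subunit, rose by 2.95 (SE 0.10), the lysyl oxidases Loxl1 and Lox by 2.92 (SE 0.09) and 2.18 (SE 0.13), and the lysyl hydroxylase Plod1 by 1.85 (SE 0.13). The 3 that fell were P4ha1 at -0.49, Bmp1 at -0.38 and P4ha2 at -0.36. Each lost its call without BLM replicate 1 (adjusted p = 0.0812, 0.111 and 0.117), without BLM replicate 2 (0.0858, 0.115 and 0.135) and without PBS replicate 1 (0.0575, 0.0736 and 0.0803), and Bmp1 and P4ha2 also without PBS replicate 2 (0.0583 and 0.0703). This list's shift (median 1.02) had an adjusted p of 2.0e-05 by camera and an adjusted p = 0.226 with an estimated correlation.

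Of 24 matrix proteases and their inhibitors, 18 rose, none fell and 6 did not pass (19 rose adjusted over the list alone). Mmp14, a membrane-bound collagenase, rose by 3.20 (SE 0.11), the protease inhibitor Timp1 by 3.12 (SE 0.16), the gelatinase Mmp2 by 3.02 (SE 0.10) and the macrophage elastase Mmp12 by 2.93 (SE 0.13). Its median was 1.19, with an adjusted p of 2.58e-10 by camera and an adjusted p = 0.226 with an estimated correlation. Macrophage markers rose on the same arrays, 15 of 20.

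Genes of the TGF-beta pathway and its targets rose in 16 of 22 cases, with none falling and 6 not passing (18 rose and 1 fell adjusted over the list alone). Ltbp2, an elastic fibre protein gene, rose by 4.10 (SE 0.09) and the TGF-beta-induced gene Pmepa1 by 2.46 (SE 0.11). Itgb6, the subunit gene of an integrin that activates TGF-beta, rose by 2.17 (SE 0.10), and Thbs1, the gene of the TGF-beta activator thrombospondin, by 1.95 (SE 0.09). The widely used target Ccn2 stood at 0.06 (-0.002 and 0.13 without PBS replicates 1 and 2) and the feedback inhibitor Smad7 at -0.25, neither past the threshold. Smad7 did pass under the filter on dim genes (adjusted p = 0.0359) and with cyclic loess (0.0385). The TGF-beta list's median was 0.90, with an adjusted p of 2.82e-08 by camera and an adjusted p = 0.226 with an estimated correlation.

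Of 23 genes of myofibroblasts and activated fibroblasts, 13 rose, 2 fell and 8 did not pass (15 rose and 2 fell adjusted over the list alone). Besides Tnc and Ltbp2, the BMP antagonist gene Grem1 rose by 3.89 (SE 0.19) and the growth factor receptor gene Pdgfrb by 2.88 (SE 0.09). Acta2, smooth muscle actin, differed by 0.07 (95% interval -0.13 to 0.28, adjusted p = 0.579) at a level of 16.47 on the PBS arrays, by 0.04 to 0.11 without each array in turn and by -0.10 with cyclic loess. Tagln stood at 0.27 and Myl9 at 0.33, passing only under the filter on dim genes (adjusted p = 0.0268 and 0.024) and with the trended robust prior (0.0411 and 0.0382), and with cyclic loess they stood at 0.09 and 0.15 (adjusted p = 0.487 and 0.284). The actin gene Actg2 rose, at 0.61, and the calponin genes Cnn1 and Cnn2 both fell, at -0.42. The calponin calls ended without BLM replicate 1 (adjusted p = 0.183 and 0.13), without BLM replicate 2 (0.0535 and 0.106) and without PBS replicate 1 (0.119 and 0.0884), and that of Cnn1 also without PBS replicate 2 (0.0877). The list's median was 0.61, with an adjusted p of 6.08e-06 by camera and an adjusted p = 0.226 with an estimated correlation.

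Alveolar fibroblast markers rose in 14 of 19 cases, fell in 3 and did not pass in 2, the same counts adjusted over the list alone. The sodium channel subunit gene Scn3b rose by 2.83 (SE 0.13), the glycogenin gene Gyg by 2.62 (SE 0.08) and the elastic fibre gene Mfap4 by 2.32 (SE 0.13). The carboxylesterase gene Ces1d fell by 2.06 (SE 0.09), and Enpep and Inmt stood at -1.02 and -0.61. Inmt lost its call without PBS replicate 2 (adjusted p = 0.0547), BLM replicate 1 (0.0836) or BLM replicate 2 (0.11). This list shifted upward by camera (median 0.60, adjusted p = 0.000655), with an adjusted p = 0.372 with an estimated correlation.

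Pericyte markers rose in 9 of 12 cases, none fell and 3 did not pass (9 rose adjusted over the list alone), with Pdgfrb at 2.88 and the cation channel gene Trpc6 at 1.63 (SE 0.11). Their median was 0.56 (camera adjusted p = 0.000646; adjusted p = 0.226 with an estimated correlation). Of 15 adventitial fibroblast genes, 7 rose, 4 fell and 4 did not pass (8 rose and 4 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.421). The microfibril gene Mfap5 rose by 3.02 (SE 0.15), and the 4 that fell were the alcohol dehydrogenase gene Adh7 at -1.50 (SE 0.10), Il33 at -1.11, Dpp4 at -0.96 and Scara5 at -0.37, which lost its call without any 1 of the arrays (adjusted p up to 0.174, without BLM replicate 1). Of 12 smooth muscle genes, 5 rose, 3 fell and 4 did not pass (6 rose and 4 fell adjusted over the list alone), and this list did not pass either (camera adjusted p = 0.676). The hedgehog antagonist gene Hhip rose by 1.56 (SE 0.08), followed by Smtn at 0.87, and the myosin gene Myh11 fell by 1.08 (SE 0.09), with Cnn1 at -0.42 and Lmod1 at -0.34. Lmod1 and Cnn1 lost their calls without any 1 of the arrays (adjusted p up to 0.2 without BLM replicate 2 and 0.183 without BLM replicate 1). Mesothelial markers rose in 6 of 11 cases, with none falling and 5 not passing (6 rose adjusted over the list alone), among them Upk1b at 2.31 (SE 0.17) and the mesothelin gene Msln at 1.28 (SE 0.10). The mesothelial call (median 0.56, camera adjusted p = 0.0463) ended with an estimated correlation (adjusted p = 0.673 with an estimated correlation), without PBS replicate 1 (0.124), without BLM replicate 2 (0.0632) and under the filter on dim genes (0.12).

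**Figure D2:**
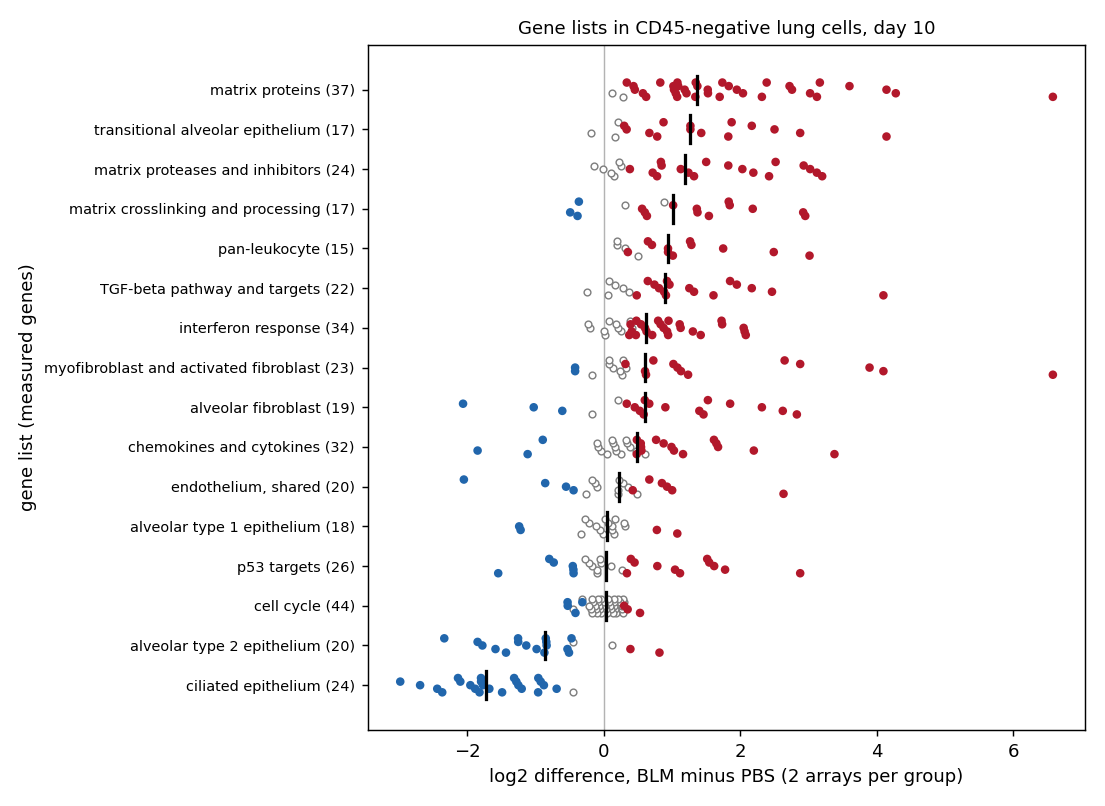
Log2 difference, BLM minus PBS (horizontal axis), of each measured gene in the main gene lists (vertical axis, number of measured genes in brackets), with filled points for genes past the threshold, open points for the others and a black bar at each list's median. Matrix proteins lie to the right with a median of 1.37 and ciliated epithelium to the left with a median of -1.72, while the medians of cell cycle, p53 target and alveolar type 1 genes lie near 0.

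Of 24 genes of ciliated epithelium, 23 fell, 18 of them at least 2-fold, none rose and only Sntn did not pass, at -0.45, although it did without PBS replicate 1, at -0.70 (adjusted p = 0.0276), against -0.19 without PBS replicate 2 (adjusted p = 0.343); adjusted over the list alone, 23 fell. Tmem212 fell by 2.98 (SE 0.13), the cadherin gene Cdhr3 by 2.69 (SE 0.11), Rsph4a, a radial spoke component of motile cilia, by 2.44 (SE 0.12) and Sec14l3 by 2.37 (SE 0.09). The list's median was -1.72 (camera adjusted p = 1.75e-22; adjusted p = 0.226 with an estimated correlation).

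Of 13 club and secretory cell genes, 10 fell, none rose and 3 did not pass (10 fell and 1 rose adjusted over the list alone), including Scgb1a1, the main club cell secretory protein gene, at -1.68 (SE 0.08) and the mucin gene Muc5b at -1.47 (SE 0.09). The club cell list had a median of -0.94 (camera adjusted p = 1.91e-06; adjusted p = 0.226 with an estimated correlation). Of 8 basal cell genes, 2 rose, 1 fell and 5 did not pass (4 rose and 1 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.487). The keratin gene Krt15 fell by 1.18 (SE 0.12). Dapl1 rose, at 0.86 (SE 0.15), as did Krt17, at 0.51. Both lost their calls without BLM replicate 1 (adjusted p = 0.0523 and 0.139), and Krt17 without PBS replicate 1 or 2 (0.081 and 0.115).

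Of 20 alveolar type 2 genes, which serve surfactant production, 16 fell, 2 rose and 2 did not pass (17 fell and 2 rose adjusted over the list alone). The thioesterase gene Acot1 fell by 2.33 (SE 0.11), the complement gene Hc by 1.85 (SE 0.10), the transcription factor gene Etv5 by 1.78 (SE 0.09) and the lamellar body gene Lamp3 by 1.58 (SE 0.08). Sftpc, surfactant protein C, differed by 0.12 (95% interval -0.18 to 0.43, adjusted p = 0.519), at levels of 19.71 and 19.84 that lie at the top of the arrays' scale, and differed by -0.03 and 0.28 without PBS replicates 1 and 2 and by -0.02 with cyclic loess. S100g was higher by 0.82 and Scd1 by 0.39. S100g lost its call without BLM replicate 1 (adjusted p = 0.0546), and Scd1 lost it without any 1 of the arrays (adjusted p = 0.057 and 0.0816 without PBS replicates 1 and 2, 0.139 and 0.0904 without BLM replicates 1 and 2), with the mean of its clusters (0.962) and with cyclic loess (0.096). The list shifted downward (median -0.86, camera adjusted p = 5.63e-10), with an adjusted p = 0.242 with an estimated correlation.

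Markers of the transitional alveolar epithelium, a keratin-rich state described in lung repair, rose in 14 of 17 cases, fell in none and did not pass in 3, with 14 rising adjusted over the list alone. Fn1, Cdkn1a and Itgb6, which other lists also hold, rose by 4.14, 2.88 (SE 0.11) and 2.17, and the tight junction gene Cldn4 by 2.5 (SE 0.11). Krt8, the keratin that names this state, differed by -0.19 (95% interval -0.47 to 0.09, adjusted p = 0.283), by -0.30 and -0.08 without BLM replicates 1 and 2 (adjusted p = 0.227 and 0.747), by -0.12 without PBS replicate 1 (adjusted p = 0.572) and by -0.37 with cyclic loess (adjusted p = 0.0527), and Fhl2 and Krt7 stood at 0.21 and 0.16. Taken as a list, they had a median of 1.27 (camera adjusted p = 1.41e-08; adjusted p = 0.226 with an estimated correlation).

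Alveolar type 1 genes mostly did not pass. Of 18 measured, 2 rose, Akap5 by 1.08 (SE 0.09) and Pdpn by 0.78 (SE 0.13), 2 fell, Lmo7 by 1.24 (SE 0.08) and Gprc5a by 1.22 (SE 0.11), and 14 did not pass, with the same counts adjusted over the list alone. Ager, the receptor gene typical of these cells, stood at 0.31 (95% interval 0.07 to 0.56, adjusted p = 0.0734, and 0.0326 under the filter on dim genes), and at 0.13 with cyclic loess (adjusted p = 0.341). The median was 0.04, the mean was -0.02 and camera's direction was downward (adjusted p = 0.676), but upward without PBS replicate 2 (adjusted p = 0.654).

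Shared endothelial genes moved both ways. Of 20 measured, 6 rose, 4 fell and 10 did not pass (7 rose and 4 fell adjusted over the list alone). The sialomucin gene Emcn rose by 2.63 (SE 0.14) and the transcription factor genes Erg and Sox18 by 1.0 (SE 0.13) and 0.93 (SE 0.08). Tmem100 fell by 2.05 (SE 0.17), Vwf, the von Willebrand factor gene, stood at -0.86, Ptprb at -0.55 and Calcrl at -0.44. Ptprb lost its call without PBS replicate 2 (adjusted p = 0.0584) or BLM replicate 2 (0.0861), and Calcrl without any 1 of the arrays (0.0648 and 0.066 without PBS replicates 1 and 2, 0.0584 and 0.116 without BLM replicates 1 and 2). Pecam1, a pan-endothelial adhesion gene, differed by 0.21 (95% interval -0.01 to 0.43, adjusted p = 0.146), and by 0.02 with cyclic loess (adjusted p = 0.852). The list as a whole did not pass (median 0.22, camera adjusted p = 0.487).

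Lymphatic endothelial markers rose in 7 of 8 cases, the same count adjusted over the list alone, with Prox1, the transcription factor that specifies lymphatic identity, at 1.90 (SE 0.09) and Mmrn1 at 1.71 (SE 0.10), while the hyaluronan receptor gene Lyve1 fell, at -1.11. Their median was 0.95 (camera adjusted p = 0.000552; adjusted p = 0.36 with an estimated correlation). Of 11 venous and bronchial-type endothelial genes, 7 rose, 2 fell and 2 did not pass, in either adjustment, that is, over all genes and adjusted over the list alone, with Lrg1 and Col15a1 both at 1.83, and with Vwf and the selectin gene Sele falling, at -0.86 and -0.58. That call (camera adjusted p = 0.0471) ended with an estimated correlation (adjusted p = 0.459 with an estimated correlation), without PBS replicate 1 (0.0881), without BLM replicate 2 (0.0556) and under the filter on dim genes (0.12). General capillary genes rose in 6 of 11 cases, fell in 2 and did not pass in 3 (6 rose and 3 fell adjusted over the list alone), led by the apelin receptor gene Aplnr at 2.62 (SE 0.09) and Plcb1 at 1.99 (SE 0.13). The 2 that fell were Ptprb at -0.55 and Hilpda at -0.48. That list did not pass (camera adjusted p = 0.114) except without PBS replicate 2 (0.0426). Of 8 aerocyte capillary genes, 5 rose, 2 fell and 1 did not pass, likewise adjusted over the list alone, with Sirpa at 1.29 (SE 0.09) and the apelin gene Apln at 1.16 (SE 0.14) rising and Fibin and Ednrb falling, at -0.76 and -0.66, and the list did not pass (camera adjusted p = 0.305). Ptprb, Hilpda and Ednrb lost their calls without BLM replicate 2 (adjusted p = 0.0861, 0.115 and 0.114), Ptprb and Ednrb without PBS replicate 2 (0.0584 and 0.0548), Ednrb without BLM replicate 1 (0.0755), and Hilpda without PBS replicate 1 or 2 (0.0763 and 0.077).

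Most pan-leukocyte and macrophage markers, 11 of 15 and 15 of 20, rose on the BLM arrays although the cells were CD45-negative. Ptprc, which encodes CD45, rose by 0.94 (SE 0.08, adjusted p = 0.00166), from 6.25 to 7.20. Of 15 pan-leukocyte genes, 11 rose, none fell and 4 did not pass (13 rose adjusted over the list alone). The signalling adaptor gene Tyrobp rose by 3.01 (SE 0.18), Laptm5 by 2.49 (SE 0.15), the integrin gene Itgb2 by 1.75 (SE 0.12) and the tetraspanin gene Cd53 by 1.28 (SE 0.09). This list's median was 0.94 (camera adjusted p = 1.62e-07; adjusted p = 0.33 with an estimated correlation). Of 20 macrophage markers, 15 rose, 1 fell and 4 did not pass (15 rose and 2 fell adjusted over the list alone), with Ctss at 5.49 and Mpeg1, a pore-forming protein gene of macrophages, at 2.90 (SE 0.11). The lysozyme gene Lyz2, which alveolar type 2 cells also express, was the marker that fell, at -1.14. Siglecf, Marco and Fabp4, among the 4 that did not pass, stood at 0.17, 0.04 and 0.01. Their ranges were 0.09 to 0.25, -0.10 to 0.18 and -0.13 to 0.14 without each array in turn. They were named because they did not pass, and the filter on dim genes left Siglecf out. They therefore do not tell which kind of macrophage the markers that rose reflect. The macrophage list had a median of 1.25 (camera adjusted p = 1.62e-07; adjusted p = 0.226 with an estimated correlation).

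Markers of other blood and thoracic cell types mostly did not pass. On the PBS arrays the median levels of the neutrophil, T and NK, B and plasma, erythroid and Schwann lists were 5.05 to 5.75. These lay below the median level of all genes, 6.03, in the range where differences are compressed toward 0. The platelet and cardiomyocyte lists lay at 7.06 and 6.425. Of 11 neutrophil genes, 4 rose, 1 fell and 6 did not pass (5 rose and 1 fell adjusted over the list alone), and the list did not pass (camera adjusted p = 0.119). The collagenase gene Mmp8 rose by 2.52 (SE 0.11), and Retnlg stood at 0.72, S100a8 at 0.65 and Il1r2 at 0.63. The lactoferrin gene Ltf fell by 1.11 (SE 0.12), from 12.88 on the PBS arrays, where the neutrophil list's median level was 5.52. S100a8 lost its call without PBS replicate 2 (adjusted p = 0.0616), BLM replicate 1 (0.137) or BLM replicate 2 (0.0843). Of 11 T and NK cell genes, 3 rose, none fell and 8 did not pass, in both adjustments, including adjusted over the list alone (camera adjusted p = 0.116). The 3 were Il7r at 0.52, Cd3d at 0.47 and Cd3g at 0.30, and all lost their calls without BLM replicate 1 (adjusted p = 0.0567, 0.0922 and 0.225) or BLM replicate 2 (0.0647, 0.0568 and 0.152), Cd3d and Cd3g also without PBS replicate 2 (0.0517 and 0.115) and Cd3g without PBS replicate 1 (0.116), with the trended robust prior (0.0614), with median centring (0.0623) and with cyclic loess (0.0578). Of 8 B and plasma cell genes, 2 fell, none rose and 6 did not pass, likewise adjusted over the list alone (camera adjusted p = 0.0727, and 0.0352 without PBS replicate 1). The 2 were the immunoglobulin gene Ighm at -2.79 (SE 0.73), a call lost without BLM replicate 1 (0.146) or BLM replicate 2 (0.0937), and Mzb1 at -0.61 (SE 0.11), lost without PBS replicate 1 (0.0569) or BLM replicate 2 (0.0691). Ighm differed between the PBS arrays, at 11.03 and 13.33, and its difference was -3.94 without PBS replicate 1 and -1.63 without PBS replicate 2. Of 6 erythroid genes 1 rose (2 adjusted over the list alone), Bpgm at 0.91 (camera adjusted p = 0.448). Of 5 platelet genes 2 fell (3 adjusted over the list alone), Ppbp at -0.96 and Itga2b at -0.68 (camera adjusted p = 0.0747, and 0.0423 without PBS replicate 1). Of 4 Schwann and neuroendocrine genes 1 rose, S100b at 0.97, and adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.676). Of 8 cardiomyocyte genes, which mark the muscle sleeve of pulmonary veins, 3 fell, none rose and 5 did not pass, also adjusted over the list alone. They were the troponin gene Tnni3 at -0.83, the myosin gene Myh6 at -0.49 and the calcium channel gene Ryr2 at -0.39. Myh6 and Ryr2 lost their calls without BLM replicate 1 (adjusted p = 0.0679 and 0.105) or BLM replicate 2 (0.0719 and 0.119), and Ryr2 without PBS replicate 1 or 2 (0.0762 and 0.0548). The cardiomyocyte list passed (median -0.21, camera adjusted p = 0.0299), but not with an estimated correlation (adjusted p = 0.33 with an estimated correlation), without PBS replicate 2 (0.0746), without BLM replicate 1 (0.0776) or under the filter on dim genes (0.104).

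Of 34 interferon response genes, 24 rose, none fell and 10 did not pass (26 rose adjusted over the list alone). Ifi27l2a rose by 2.08 (SE 0.15), the antiviral membrane protein gene Bst2 by 2.06 (SE 0.17) and the RNA sensor gene Oas1a by 2.05 (SE 0.11). Ifit1 rose by 1.74 (SE 0.42), a call lost without BLM replicate 1 (adjusted p = 0.112) or BLM replicate 2 (adjusted p = 0.0998). Its PBS values were 5.63 and 6.99, and its difference was 1.06 without PBS replicate 1 and 2.41 without PBS replicate 2. The interferon list's median was 0.62 (camera adjusted p = 7.99e-08; adjusted p = 0.36 with an estimated correlation). Of 32 chemokines and cytokines, 15 rose, 3 fell and 14 did not pass (17 rose and 3 fell adjusted over the list alone). Cxcl14 rose by 3.38 (SE 0.13), the monocyte attractant gene Ccl8 by 2.20 (SE 0.09) and the inflammatory cytokine gene Il1b by 1.68 (SE 0.14). Ccl3 fell by 1.85 (SE 0.09), the alarmin gene Il33 stood at -1.11 and Ccl4 at -0.89. Its median was 0.48 (camera adjusted p = 0.000961; adjusted p = 0.372 with an estimated correlation). The rise of pan-leukocyte markers, 11 of 15, lay on the same arrays.

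Complement and acute phase genes rose in 8 of 12 cases, none fell and 4 did not pass (8 rose and 1 fell adjusted over the list alone), led by the protease inhibitor gene Serpina3n at 3.85 (SE 0.29) and the serum amyloid gene Saa3 at 2.30 (SE 0.10). Their median was 1.09 (camera adjusted p = 0.000552; adjusted p = 0.226 with an estimated correlation). Of 8 MHC class II genes, which present antigen, 5 fell, none rose and 3 did not pass (6 fell adjusted over the list alone). The 5 were H2-DMb2 at -0.79, H2-Aa at -0.77, H2-DMb1 at -0.74 and H2-Ab1 and H2-Eb1 at -0.60. H2-Ab1 and H2-Eb1 lost their calls without BLM replicate 2 (adjusted p = 0.0517 and 0.0592), and H2-Eb1 without BLM replicate 1 (0.0526). The class II list had a median of -0.60 (camera adjusted p = 4.6e-05; adjusted p = 0.226 with an estimated correlation).

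Of 26 Wnt pathway genes, 9 rose, 1 fell and 16 did not pass (12 rose and 1 fell adjusted over the list alone). Sfrp1 rose by 4.63 and the Wnt inhibitor gene Dkk2 by 1.84 (SE 0.14), the feedback inhibitor gene Nkd1 fell, at -1.51, and the target gene Axin2 stood at 0.32, not passing except under the filter on dim genes (adjusted p = 0.0355), and at 0.21 and 0.42 without PBS replicates 1 and 2 (adjusted p = 0.213 and 0.0514). The Wnt list passed (median 0.21, camera adjusted p = 0.0209), but not under that filter (0.112) and not with an estimated correlation (adjusted p = 0.33 with an estimated correlation). Glycolysis and hypoxia genes rose in 9 of 17 cases, fell in 3 and did not pass in 5 (10 rose and 3 fell adjusted over the list alone), with the hypoxia-induced gene Ankrd37 at 2.67 (SE 0.09) and the vasodilator peptide gene Adm at 1.24 (SE 0.13). The hexokinase gene Hk2 fell, at -0.78, and Bnip3 and Pdk1 stood at -0.43 and -0.40. Bnip3 and Pdk1 lost their calls without PBS replicate 2 (adjusted p = 0.109 and 0.0941), BLM replicate 1 (0.141 and 0.0661) or BLM replicate 2 (0.155 and 0.174), and Pdk1 without PBS replicate 1 (0.104). The glycolysis call (median 0.30, camera adjusted p = 0.0471) ended with an estimated correlation (adjusted p = 0.448 with an estimated correlation), without PBS replicate 1 (0.0916) or BLM replicate 1 (0.0776), under the filter on dim genes (0.12), with the mean of a gene's clusters (0.0542), with cyclic loess (0.0635) and without the X and Y genes (0.083).

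Lipid synthesis genes fell in 8 of 14 cases, rose in 4 and did not pass in 2, in both adjustments, including adjusted over the list alone, with the acyltransferase gene Gpam at -1.86 (SE 0.08) and the sterol-regulated gene Insig1 at -1.36 (SE 0.08). The 4 that rose were Elovl6 at 0.83, Fdps at 0.74, Hmgcs1 at 0.44 and Scd1 at 0.39. Of these, Fdps, Hmgcs1 and Scd1 lost their calls without BLM replicate 1 (adjusted p = 0.0624, 0.132 and 0.139), Hmgcs1 and Scd1 without PBS replicate 1 (0.0984 and 0.057) or BLM replicate 2 (0.138 and 0.0904), and Scd1 without PBS replicate 2 (0.0816). With cyclic loess Hmgcs1 and Scd1 did not pass (0.0536 and 0.096), nor did Hmgcs1 with median centring (0.0513) or Scd1 with the mean of its clusters (0.962). The lipid list had a median of -0.39 (camera adjusted p = 0.00857; adjusted p = 0.269 with an estimated correlation). Of 13 antioxidant genes under NRF2, 6 fell, 2 rose and 5 did not pass (6 fell and 4 rose adjusted over the list alone), with the glutathione genes Gsta3 at -2.79 (SE 0.15) and Gclc at -2.73 (SE 0.12) falling and the extracellular enzyme genes Sod3 and Gpx3 rising, at 1.78 and 1.47. The antioxidant list did not pass (camera adjusted p = 0.104) except without PBS replicate 1 (0.0257). Of 4 mitochondrially encoded RNAs, 3 fell and 1 did not pass, likewise adjusted over the list alone, with ND2 at -2.24 (SE 0.09), ND6 at -1.85 (SE 0.21), COX2 at -0.51 and COX1 not passing, at -0.10 (-0.22 to 0.02 without each array in turn). COX2 lost its call without BLM replicate 1 (adjusted p = 0.0825) or BLM replicate 2 (0.0649). The mitochondrial list had a median of -1.18 (camera adjusted p = 0.00192; adjusted p = 0.242 with an estimated correlation). Of 20 unfolded protein response genes, 7 rose, 1 fell and 12 did not pass (10 rose and 3 fell adjusted over the list alone), with Ddit3 at 0.85 (SE 0.10) and Herpud1 at -1.63 (SE 0.09), and the list did not pass (camera adjusted p = 0.171). Of 16 immediate early and heat shock genes, 3 rose, 5 fell and 8 did not pass (4 rose and 7 fell adjusted over the list alone), with the stress-induced factor gene Atf3 at -1.20 (SE 0.08), Ier2 at -0.82, Jun and Fos at -0.50 and Hsp90aa1 at -0.48. Those that rose were Ier3 at 0.83 (SE 0.17), Hspa1a at 0.58 and Egr2 at 0.49. Of these 8, only Atf3 and Ier2 kept their calls without each array in turn, the adjusted p of the others reaching 0.0696 for Jun, 0.163 for Fos, 0.088 for Hsp90aa1, 0.0831 for Ier3 and 0.168 for Egr2 without BLM replicate 2, and 0.0976 for Hspa1a without BLM replicate 1. Egr2 also lost its call with median centring (0.0533) and cyclic loess (0.0666). That list's camera adjusted p was 0.0968, and it passed downward without PBS replicate 1 (0.0332) and with cyclic loess (0.0485). Of 12 ribosomal protein genes 2 rose, also adjusted over the list alone, Rps18 at 0.45 and Rpl19 at 0.41, and 10 did not pass (camera adjusted p = 0.416). Rps18 lost its call without BLM replicate 1 (adjusted p = 0.083), BLM replicate 2 (0.0864) or PBS replicate 1 (0.0587), and Rpl19 without any 1 of the arrays (0.0768 and 0.0556 without PBS replicates 1 and 2, 0.0802 and 0.125 without BLM replicates 1 and 2) and with cyclic loess (0.0962).

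Targets of p53, the DNA damage response factor, went both ways. Of 26 measured, 11 rose, 6 fell and 9 did not pass (12 rose and 7 fell adjusted over the list alone). Cdkn1a, the cell cycle inhibitor p21, rose by 2.88, the death receptor genes Tnfrsf10b and Eda2r by 1.78 (SE 0.08) and 1.62 (SE 0.13), and Ccng1 by 1.55 (SE 0.11). The deepest falls were those of Dcxr at -1.54, Trp53inp1 at -0.80 and Perp at -0.73. The list as a whole did not pass (median 0.03, camera adjusted p = 0.539).

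Of 44 cell cycle genes, 3 rose, 4 fell and 37 did not pass, and adjusted over the list alone 1 rose and 3 fell. The proliferation marker Mki67 differed by -0.21 (95% interval -0.50 to 0.07, adjusted p = 0.236) at a level of 12.79 on the PBS arrays, by -0.08 and -0.34 without PBS replicates 1 and 2 (adjusted p = 0.603 and 0.0821), and by -0.40 with cyclic loess (adjusted p = 0.0565). The genes past the threshold were Cenpa at 0.53, Ccnb2 at 0.35, Rrm2 at 0.30, Prc1 and Kif11 at -0.53, Cenpf at -0.41 and Pcna at -0.31. All but Cenpa lost their calls without BLM replicate 2 (adjusted p from 0.0675 for Kif11 to 0.22 for Pcna) and all but Kif11 without BLM replicate 1 (from 0.0716 for Prc1 to 0.199 for Rrm2). Ccnb2, Rrm2, Cenpf and Pcna lost them also without PBS replicate 1 (0.113, 0.0908, 0.0581 and 0.122), and these and Cenpa without PBS replicate 2 (0.0751, 0.142, 0.0741, 0.109 and 0.0657). Rrm2 also lost its call with median centring (0.0611) and cyclic loess (0.0562), and Pcna stood at -0.50 with cyclic loess. The list did not pass (median 0.03, mean 0.01, camera's direction downward with an adjusted p of 0.646).

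**Figure D3:**
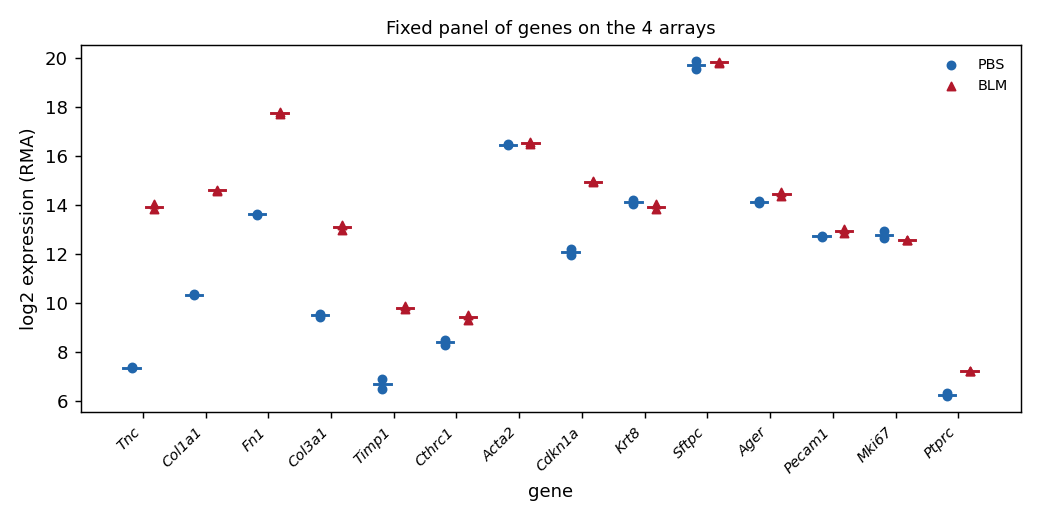
Log2 expression (vertical axis) of the fixed panel of genes (horizontal axis) on each PBS array (circles) and BLM array (triangles), with a bar at each group's mean of 2 arrays. Tnc, Col1a1, Fn1, Col3a1, Timp1, Cthrc1, Cdkn1a and Ptprc lie higher on both BLM arrays and past the threshold, while Acta2, Krt8, Sftpc, Ager, Pecam1 and Mki67 did not pass.

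The p-values rest on 2 arrays per group and measure the spread between these samples, and 25 of 44 gene lists passed with the preset correlation, 18 upward and 7 downward. No list kept its call with an estimated correlation in a test that has only 2 degrees of freedom. With those correlations held fixed, or 0 where negative, 18 of the 25 calls were kept. This alternative was chosen after the list results were seen. The calls of alveolar fibroblasts, interferon response, chemokines and cytokines, lymphatic, venous and mesothelial markers and glycolysis ended there. Where the estimate lay below the preset 0.01, that test was more lenient than the main one, so a kept call adds little. Because sex-linked transcripts and treatment separate the 4 arrays in the same way, no fit of these arrays can hold them apart.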

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

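The tests of explanations in this part, and the count without X and Y genes, were chosen only after the results were seen.

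Transcripts of the Y chromosome, used in the report only to check the samples, were higher on the BLM arrays: Eif2s3y by 2.63, Uty by 2.44 and Kdm5d by 2.14 log2 units, while Xist differed by -10.22. The values needed if the PBS samples came from female and the BLM samples from male mice were there: the 4 X genes known to escape inactivation, Kdm6a, Kdm5c, Eif2s3x and Ddx3x, were all lower on the BLM arrays, with a median of -0.797. Sex may therefore have contributed to any call, since the 7289 calls on genes outside the X and Y chromosomes cannot be told apart from calls by sex while sex-linked expression and treatment align on all 4 arrays. An effect of BLM on those genes stays open as well, and no array here separates them.

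Transcript clusters without a single gene name took no part in the comparison. Of 35352 such clusters, 11.2% passed the threshold when tested by themselves, 1113 higher and 2838 lower in BLM, of which 477 and 1298 differed at least 2-fold.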

How the results depend on the processing

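The alternatives were fixed before the data were examined, except the one without X and Y genes and the one with the estimated correlation held fixed, which were chosen after the sex-linked values and the list results were seen. Leaving out each array in turn, with the lone array assumed to vary like the other group, gave 4003 to 5956 calls against 7629, with 2333 to 3521 higher and 1670 to 2435 lower. The lowest totals came without BLM replicate 1 (4003) and BLM replicate 2 (4379). Each such fit has fewer arrays, and takes its spread only from the group left whole. Without a BLM array that is the PBS pair, whose difference across genes had an SD of 0.216, against 0.185 for the BLM pair. A call lost without a BLM array therefore need not rest on that array. Of the 4003 calls, 3900 were among the 7629. The count at least 2-fold lay between 1481 and 1732 in all settings run. The other totals were 8050 of 15071 genes with the filter on dim genes, 7599 with the mean of a gene's clusters, 8007 with the trended robust prior, 7406 with median centring, 7716 with cyclic loess and 7444 without X and Y genes. Of the 238 genes named in the text, 180 kept their side of the threshold in every setting that tested them and 171 of these also their direction; the other 9, which passed in no setting, changed sign in at least 1 (Acta2, Sftpc, Ccn2, Col14a1, Marco, Fabp4, COX1, Dnah17 and Cfap97). Of the 44 gene lists, 34 kept their side of the threshold in every setting but those with an estimated correlation and 32 of these also their direction; alveolar type 1 and basal epithelium, which did not pass, changed it. No named gene or list with a call in any setting reversed.

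With the correlation estimated from the arrays, all 25 list calls ended, but that test refers its statistic to 2 degrees of freedom and gave no list an adjusted p below 0.226, so it says little of how stable a list is. With each estimated correlation held fixed (0 where negative) and the degrees of freedom of the preset test, 18 of the 25 calls were kept. Those of alveolar fibroblasts (0.108), interferon response (0.0650), chemokines and cytokines (0.132), lymphatic endothelium (0.0851), venous endothelium (0.255), mesothelium (0.572) and glycolysis and hypoxia (0.233) ended. For lists whose estimate lay below the preset 0.01, such as matrix proteins at -0.024, this test was more lenient than the main one, so a kept call adds little. In the test on 2 degrees of freedom the adjusted p was 0.2261 for matrix proteins, crosslinking, proteases, myofibroblasts, transitional epithelium, ciliated epithelium and the TGF-beta list, 0.2418 for alveolar type 2 epithelium, 0.3295 for pan-leukocyte genes, 0.3595 for interferon response and 0.3723 for alveolar fibroblasts and for chemokines and cytokines. With the replicate block the total was 6742 calls, 6445 of them among the 7629, and of the list calls it ended only that of glycolysis and hypoxia (camera adjusted p = 0.0597); of the named genes it ended the calls of 11. The labels tie same-numbered samples by nothing but the number. Deviations of same-numbered arrays correlated at 0.014 across genes, which cannot tell whether they shared a batch. No detection calls were used, and the median level of all genes, 6.03, compares with a background median of 3.60 to 3.75 per array, so differences of genes near that background are the least certain.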

Other observations

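All tests of explanations in this part were chosen only after the results were seen, and so were the gene families described.

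Most members of both families of cilium genes examined fell on the BLM arrays. Of 14 axonemal dynein heavy chain genes, which drive ciliary beating, 11 fell, with Dnah6 at -2.52 and Dnah12 at -2.11, and 3 did not pass, Dnah14 at 0.05, Dnah17 at 0.04 and Dnah8 at -0.23. Of 31 genes of the cilia and flagella associated family, 27 fell, 17 of them at least 2-fold, with Cfap65 at -2.43 and Cfap69 at -2.18, and 4 did not pass, Cfap410 at 0.08, Cfap97 at 0.05, Cfap36 at -0.20 and Cfap73 at -0.38 (-0.25 without BLM replicate 1), although Cfap36 did with cyclic loess (adjusted p = 0.0335), which also took Dnah17 and Cfap97 below 0. Dnah5, Dnah9, Cfap126 and Cfap44 also belong to the ciliated list. Of 14 carboxylesterase 1 and flavin monooxygenase genes 8 fell, among them Fmo2 at -2.16 and Ces1e at -2.05. Of 45 Cyp2 genes 10 fell, while Cyp2e1 at 0.79, Cyp2j6 at 0.78 and Cyp2j9 at 0.73 rose and 32 did not pass. The Cyp2 median was 0.0005, and 25.3% of all genes tested passed. The Cyp2 genes that did not pass lay below the median level of all genes, 6.03. Without each array in turn, Cyp2j6 stood at 0.63 to 0.935 and Cyp2j9 at 0.53 to 0.93. Of 9 mast cell and basophil genes 4 fell, Mcpt8 at -3.74, Cpa3 at -1.18, Ms4a2 at -0.96 and Gata2 at -0.92, and 5 did not pass.

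Most macrophage and pan-leukocyte markers rose on the BLM arrays although the sort should remove cells with CD45. Macrophages left in the BLM fraction cannot be told apart from expression of these genes by CD45-negative cells: 75% of the 20 macrophage markers rose, and Ptprc rose as well, but these are the genes that make up the pattern. Ctss went from 7.48 on the PBS arrays to 12.96 on the BLM arrays and Mpeg1 from 6.70 to 9.60; on the PBS arrays 3 of the markers had a signal above the upper quartile of all genes, and no other list holds any of them. Whether all leukocyte types were left alike cannot be told apart from macrophages alone: the macrophage median exceeded that of T, NK and B cell markers by 1.22, but only 2 of those 19 markers lay above the median level of all genes. Mast cell and basophil genes did not share the rise, since 4 of 9 fell and none rose. Those genes were chosen after their values were seen and 5 of them did not pass, so they are no separate test.

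Clock genes of opposite phases moved in opposite directions. The 4 genes of the Arntl phase rose (Arntl by 3.54, Npas2 by 1.86, Nfil3 by 0.76 and Clock by 0.49), and 11 of 12 genes of the opposite phase fell, among them Per2 at -3.19, Per3 at -3.16, Wee1 at -2.60 and Tef at -2.24, with Nr1d1 at -0.62 not passing, although it did without PBS replicate 1 (adjusted p = 0.0107), under the filter on dim genes (0.0295), with the trended robust prior (0.0494) and with cyclic loess (0.033). Nr1d1 stood at -0.88 without PBS replicate 1 and at -0.36 without PBS replicate 2 (adjusted p = 0.0768). Clock lost its call without BLM replicate 1 (0.0807) or BLM replicate 2 (0.0501) and stood at 0.32 with cyclic loess. Fewer cells of the types that express clock genes would lower both arms, whereas the Arntl-phase median was 1.31, with a lowest interval bound of 0.28. The rise of these 4 genes goes against such a loss as the whole account. It is part of the pattern itself, on genes chosen after their values were seen, so it is no separate test. That 93.8% of the 16 clock genes passed in the direction of their phase only restates the pattern on genes chosen for it. Samples taken at different times of day therefore cannot be told apart from an effect of BLM or of sex on the clock, and the labels give no time of day.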
